A study of Mus musculus with 2 samples.

How the data were processed

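Single-cell RNA sequencing was done on CD45+CD11b+ cells sorted from the cerebral cortex of 8-week-old mice, with 1 library from wild-type mice and 1 from mice lacking Msn, the gene of moesin. Per the labels' protocols, the cortices of 5 to 6 mice of each genotype were pooled, digested with papain, cleared on a Percoll gradient, sorted with antibodies against CD45 and CD11b, and loaded on the 10x Genomics 3′ v2 chemistry. The groups were taken from the genotype field of the labels. The series design names C57BL/6 for the knockout mice. The strain of the wild-type mice, the sex of the animals and the part of Msn that was deleted are not given in the sources used here.

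The deposited matrices hold whole-number UMI counts per gene and barcode, made with Cell Ranger, per the file headers (version 7.0.0), while the labels' protocols name version 6.0. The genome build was GRCm39, per the labels' protocols. Seurat was named for quality control, with a filter on cells under 500 genes, per the labels' protocols. That filter had not been applied to the deposited counts, which include barcodes under it in both libraries and start at 500 UMIs per barcode. Each matrix lists 55357 genes, of which 54749 (98.9%) were matched by identifier to the GENCODE mouse annotation on GRCm39, from which all coordinates were taken.

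Barcodes with at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes were kept, after doublets had been called per library with a reimplementation of the Scrublet method (expected rate 0.06). The caller marked 15 wild-type barcodes (0.269%) and 2 knockout barcodes (0.0264%). Such low shares mean that the caller had not worked, so doublets remained among the kept cells. Both libraries were clustered together on 2000 variable genes, chosen by their mean dispersion rank over the libraries, without Msn, sex-linked, mitochondrially encoded and ribosomal protein genes. The clustering used 30 principal components, 15 neighbours and the Leiden method at resolution 0.6. Clusters were named from 16 fixed marker lists. A cluster took the name of the class with the highest marker level among those with at least 3 markers detected in 20% of its cells and a level at or above the mean of clusters. It stayed unnamed where its top gene was a marker of another class, or where another class had more markers than its own among its 10 leading genes. It also stayed unnamed where its median UMI count was under its library's median divided by 3 with no marker of the class among those genes, or where at least 2 markers of another class led it within its own class.

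The marker lists were fixed beforehand, but the naming rule was written after the clusters had been seen and was revised several times. Levels were changed from sums to means of log values because single cells full of hemoglobin RNA had named clusters, and because large microglial clusters had stayed unnamed without the mitochondrial filter and with at least 1000 genes per cell. The demand for a level at the mean of clusters was added because a cluster with basophil genes had been named microglia. In the last revisions, a cluster with a median above 2.5 times the library's median UMI count and a marker of another class among its 20 leading genes was left unnamed. A cell of a named class other than microglia was left unnamed when its summed microglia markers reached the median of microglia-like cells divided by 3, that is 9644 CPM. The shares that the last 2 rules kept out are given with the composition.

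For expression, UMI counts were summed over the microglia-like cells of each library and divided by their total to give CPM, counts per mega-count of UMIs. The log2 ratio of knockout over wild-type was computed for genes at 10 CPM or more in at least 1 library. A gene was called higher or lower by size alone, at 1.5-fold or more. With 1 library per genotype there was no replicate check, so no test was made and no p-value or standard error is given. Intervals are 95% and exact (Poisson for sums, conditional for ratios, binomial for shares). They cover counting error only, not differences between mice, sorts or libraries. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs, leaving out shallower cells. The 20 gene lists, the markers, the 20 state genes, the rule for named genes and most alternatives were fixed before the data were examined. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The middle 95% of random lists was taken as between. The lists overlap: Selplg, Trem2, Lpl, Apoe, Cx3cr1 and others stand in several, and homeostatic genes also serve as microglia markers.

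The named genes are, in microglia-like cells, the 12 with the highest and the 12 with the lowest log2 ratio among genes at 50 CPM or more in at least 1 library, leaving out mitochondrially encoded, ribosomal protein and sex-linked genes. Msn, Ezr and Rdx are named too, and in each list up to 4 measured members with the largest absolute log2 ratio. Other members named beside these are examples chosen after their values were seen.

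Poisson counts were simulated for the knockout against wild-type comparison of microglia-like cells. Of 8183 unchanged genes, 0% passed the 1.5-fold rule, and the ratio's interval covered the true value for 95.5%. These counts held counting error only, without differences between mice, sorts or libraries, so they give no rate of false calls for the real data. Of 40 genes at each of the true folds 0.25, 0.5, 2 and 4, 100% passed, and of 40 at exactly 1.5-fold, 5% passed. In 8383 simulated genes, a list of 20 at 1.5-fold reached percentile 100 and a list of 20 unchanged genes percentile 31.3.

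The alternatives covered filters, doublets, cluster resolution, cell class, scaling, expression floor, size rule and thinning, and some were added after the data had been seen. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.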

Results

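The study asked how the loss of moesin, a protein of the ezrin-radixin-moesin (ERM) family that links the plasma membrane to cortical actin, alters microglia of the adult cerebral cortex. CD45 and CD11b, the proteins used for sorting, are carried by microglia and by other myeloid cells. The wild-type library held 5842 barcodes and 68576464 UMIs, with medians of 6706 UMIs and 2698 genes per barcode. The knockout library held 9038 barcodes and 67575835 UMIs, with medians of 4816 UMIs and 1933 genes. Mitochondrially encoded genes made up a median of 1.45% of UMIs in the wild-type library and 0.557% in the knockout library. Barcodes under 500 genes numbered 207 (3.54%) in the wild-type library and 1463 (16.2%) in the knockout library. After filtering, 5562 wild-type cells (median 7146.5 UMIs) and 7571 knockout cells (median 5454 UMIs) were kept. Each genotype was represented by 1 library pooled over mice, so genotype and library could not be separated and no difference below has a replicate check.

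Msn RNA was far lower in the knockout library in each class with enough cells to compare. In microglia-like cells Msn (ENSMUSG00000031207, chromosome X, 95139129 to 95212557, GRCm39) stood at 321 CPM (317 to 326, exact 95% Poisson interval) in the wild-type library and 20.5 CPM (19.1 to 22.0) in the knockout library. The log2 ratio was −3.97 (−4.08 to −3.87), a 15.7-fold lower level. In border-associated macrophage-like cells Msn was 319 CPM (259 to 388) against 17.9 CPM (11.1 to 27.4), and in monocyte-like cells 849 CPM (764 to 941) against 56.3 CPM (49.5 to 63.9). The knockout library thus kept 5.62 to 6.64% of the wild-type Msn level over these 3 classes. With every cell thinned to 2000 UMIs, 46.6% (45.2 to 48.0) of 4952 wild-type and 3.85% (3.29 to 4.47) of 4233 knockout microglia-like cells had an Msn UMI, with 221 and 337 shallower cells left out. Without thinning the shares were 85.1% and 14.1%, at median depths of 7180 and 5658 UMIs. No class that lacks Msn in wild-type mice was available as a background. The labels do not say which part of the gene was deleted, and a 3′ tag outside a deleted part would not report on the deletion.

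**Figure D1:**
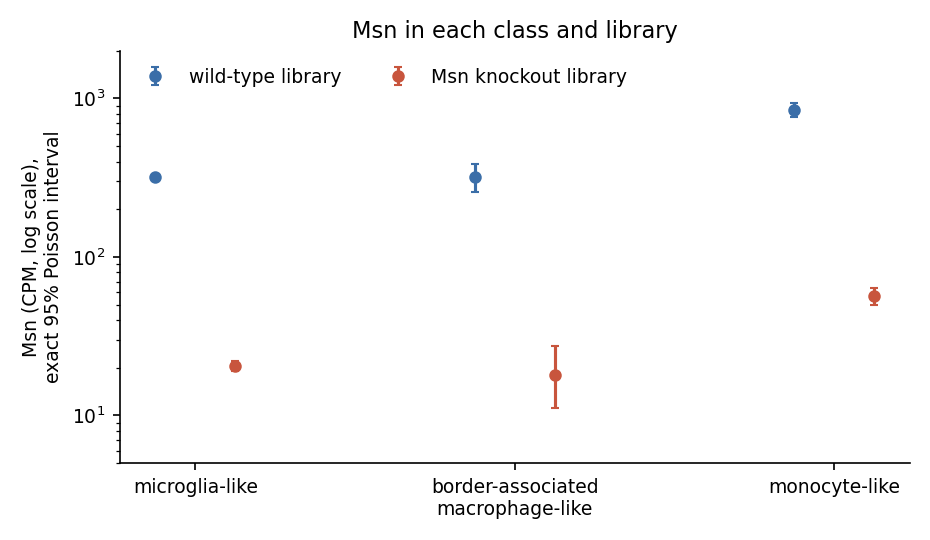
Msn in CPM on a log axis for microglia-like, border-associated macrophage-like and monocyte-like cells of the wild-type (blue) and Msn knockout (red) libraries, with exact 95% Poisson intervals. The knockout points lie at 20.5, 17.9 and 56.3 CPM, below the wild-type points at 321, 319 and 849 CPM.

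The knockout library held a smaller share of microglia and larger shares of monocytes, border-associated macrophages (macrophages of the meninges and perivascular spaces) and lymphoid cells. Microglia-like cells made up 93.0% of kept wild-type cells (92.3 to 93.7, exact binomial, 5173 cells) and 60.4% of kept knockout cells (59.2 to 61.5, 4570 cells). Monocyte-like cells made up 1.04% (0.793 to 1.35, 58 cells) against 9.69% (9.04 to 10.4, 734 cells), a share 9.30-fold higher in the knockout library (7.11 to 12.4). Most of them lay in cluster 5, with 35 wild-type and 602 knockout cells and Ace and Treml4, genes of patrolling monocytes, among its leading genes. The others lay in cluster 11, with 23 and 132 cells and Ly6c2 and Chil3, genes of classical monocytes. Border-associated macrophage-like cells made up 1.01% (0.761 to 1.31, 56 cells) against 3.32% (2.92 to 3.74, 251 cells), a 3.29-fold higher share (2.46 to 4.48). Natural killer (NK) cell-like cells numbered 1 of 5562 in the wild-type library and 87 of 7571 in the knockout library (1.15%, 0.921 to 1.42). B cell-like cells numbered 2 against 33 (12.1-fold), and neutrophil-like cells 3 against 30. These small classes depended on the settings: with at most 5% mitochondrial UMIs, B cell-like cells numbered 21 against 113 (3.87-fold). Without the mitochondrial filter, with at least 1000 genes per cell, or without the highest 6% of doublet scores, no B cell-like or neutrophil-like cluster was named, and at resolution 0.3 no neutrophil-like cluster. All shares are of CD45+CD11b+ sorted barcodes with 500 UMIs or more in libraries of unlike median depth, and NK and B cells were not the target of that sort.

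**Figure D2:**
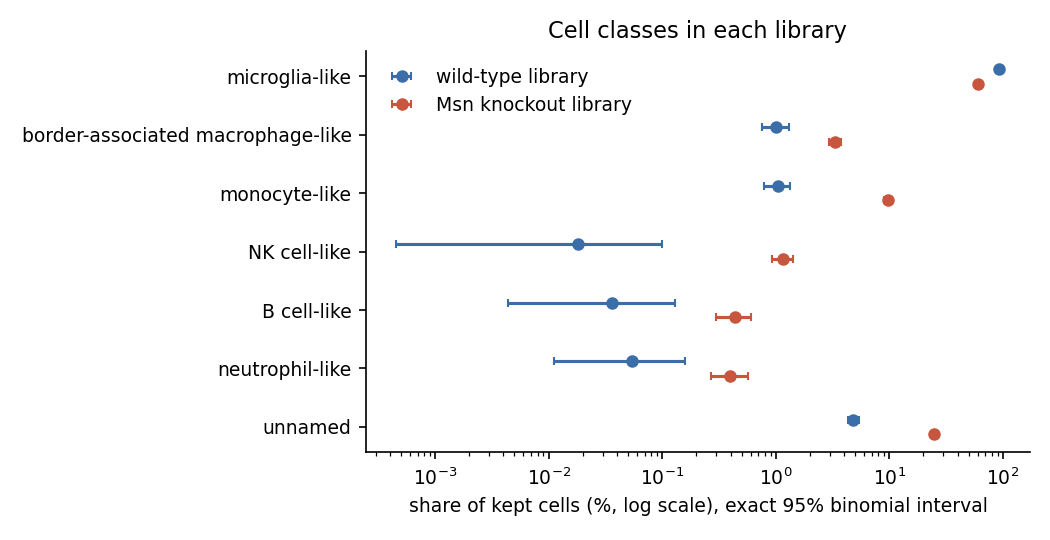
Share of kept cells in each named class, in percent on a log axis, for the wild-type (blue) and Msn knockout (red) libraries, with exact 95% binomial intervals. Monocyte-like cells stand at 1.04% and 9.69%, and microglia-like cells at 93.0% and 60.4%.

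Unnamed cells made up 4.84% of the wild-type library (269 cells) and 24.6% of the knockout library (1866 cells), and the naming rule, written and revised after the clusters had been seen, left out many of them. Cells of other named clusters that also held microglial RNA at 9644 CPM or more of summed markers numbered 151 of 271 in the wild-type library (2.71% of kept cells) and 751 of 1886 in the knockout library (9.92%). Such cells had a median of 14350 UMIs in the wild-type and 8670 in the knockout library, against 6089.5 and 4893 for the cells that kept their names. They made up 70.4% of the border-associated macrophage clusters in the wild-type and 71.4% in the knockout library, and 20 wild-type and 139 knockout cells of all classes lay near the limit. With them counted in, border-associated macrophage-like shares were 3.40% and 11.6%. Of the border-associated macrophage clusters, cluster 10 was led by the major histocompatibility complex (MHC) class II genes H2-Aa, H2-Eb1 and H2-Ab1 and also held the dendritic cell marker Cd209a. Unnamed cluster 8, with microglial markers plus Plac8, a monocyte marker, and medians of 19853 and 18922 UMIs, held 0.647% of wild-type and 5.38% of knockout cells. Unnamed cluster 4, with medians of 1140 and 887.5 UMIs, held 1.38% and 8.00%.

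Microglia-like cells of the 2 libraries differed in expression across much of the transcriptome, with the heat shock genes Hspa1a and Hspa1b, Klf2 and nuclear-encoded oxidative phosphorylation genes higher in the knockout library and Msn, mitochondrially encoded RNA and the nuclear RNA Neat1 lower. Summed UMIs came to 63302625 in the wild-type and 38303056 in the knockout library. Over 8694 measured genes the median log2 ratio was −0.29, so that 356 genes were at least 1.5-fold higher and 2611 at least 1.5-fold lower on the CPM scale. Relative to that median, 1276 genes were higher and 1039 lower, with 6379 within 1.5-fold. The share of higher genes among those past the rule was 11.999% on the CPM scale and 55.1% relative to the median. Median-of-ratios scaling shifted all ratios by 0.43 and gave 1907 higher and 599 lower. Log2 ratios and counts for microglia-like cells below are therefore relative to the median of all measured genes, which no scaling factor moves. The libraries met little within clusters: clusters 1 and 2 held 2467 and 2258 of the wild-type cells but 78 and 5 of the knockout cells, while clusters 0 and 3 held 110 and 27 wild-type and 2733 and 1461 knockout cells. Cluster 3 was led within its class by the stress genes Hspa1a and Dnajb1, and cluster 15 (49 wild-type and 9 knockout cells) by the interferon genes Ifit2, Ifit3 and Mx1.

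**Figure D3:**
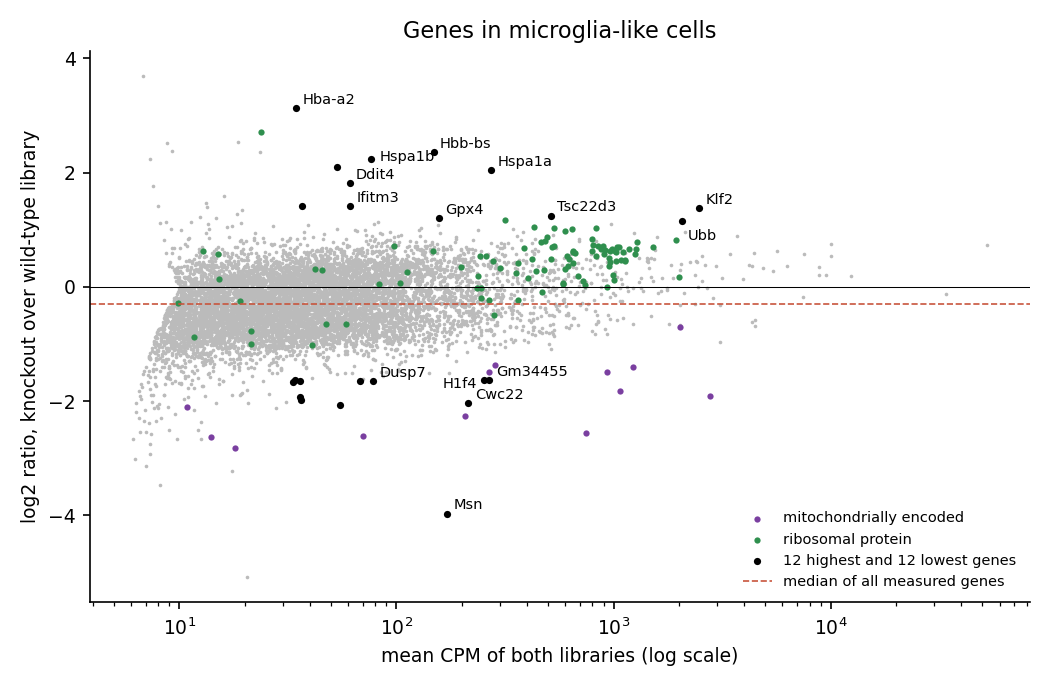
Log2 ratio of knockout over wild-type library against mean CPM of both libraries on a log axis, for 8694 genes in microglia-like cells, with the 12 highest and 12 lowest named genes in black, mitochondrially encoded genes in purple, ribosomal protein genes in green and the median of all genes (−0.29) dashed. Msn lies at −3.97, and mitochondrially encoded genes lie below most other genes of their level.

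The highest genes in knockout microglia-like cells were of varied function, among them Hspa1a, Hspa1b, Klf2 and hemoglobin genes. The heat shock protein 70 genes Hspa1b and Hspa1a stood at 26.8 and 107 CPM in the wild-type and 126 and 441 CPM in the knockout library, with relative log2 ratios of 2.53 (2.45 to 2.61) and 2.34 (2.30 to 2.38). Ddit4, a stress-induced inhibitor of mTORC1, went from 27.0 to 95.1 CPM (2.11), and Tsc22d3, a glucocorticoid-induced gene, from 304 to 722 CPM (1.54). Klf2, a transcription factor of quiescent immune and endothelial cells, went from 1378 to 3570 CPM (1.67, 1.66 to 1.68). Ifitm3, an interferon-induced membrane protein, stood at 33.4 and 89.0 CPM (1.71), the chemokine receptor gene Ccr6 at 20.1 and 53.7 CPM (1.71), the glutathione peroxidase gene Gpx4 at 95.1 and 220.01 CPM, and the ubiquitin gene Ubb at 1281 and 2834 CPM (1.44). The hemoglobin genes Hba-a2, Hbb-bs and Hba-a1 had relative log2 ratios of 3.43, 2.66 and 2.39, from 7.05, 48.3 and 20.3 CPM to 61.8, 249 and 86.8 CPM. Their RNA sat in few cells: 10 cells held 97.6%, 95.9% and 97.8% of the knockout UMIs of Hba-a2, Hbb-bs and Hba-a1. In cells with at least 1000 genes, the CPM log2 ratios fell from 3.13, 2.36 and 2.10 to 2.25, 1.39 and 1.11.

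Predicted genes and protein-coding genes of varied function followed Msn among the lowest genes in knockout microglia-like cells. Of the 12 lowest genes, 7 carried predicted-gene or small nuclear RNA names. Gm44860 went from 89.2 to 21.3 CPM (−1.77), Gm36638 from 57.9 to 14.7 CPM (−1.68), Gm37082 from 56.7 to 14.96 CPM (−1.63) and Gm34455, a long noncoding RNA, from 406 to 130.3 CPM (−1.35). Gm44668 and Gm43462 were lower by a similar amount (−1.37 and −1.36), as was Rnu11, the U11 RNA of the minor spliceosome (−1.36). The protein-coding members were the splicing factor gene Cwc22, from 345 to 84.3 CPM (−1.74, −1.79 to −1.69), the linker histone gene H1f4, from 384 to 124 CPM (−1.34), Dusp7, a phosphatase of ERK kinases, from 119 to 37.8 CPM (−1.36), and Rabepk, from 51.5 to 16.7 CPM (−1.33). Below the expression floor of the named-gene rule, and chosen after their values were seen, Gm43221 stood at 40.0 CPM (2531 UMIs) against 1.17 CPM (45 UMIs; −4.79, −5.25 to −4.37) and the glutaminyl cyclase gene Qpct at 31.7 against 3.39 CPM (−2.93, −3.19 to −2.67).

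The other ERM genes did not share the low level of Msn in knockout microglia-like cells. Rdx (chromosome 9, 51958473 to 52015538), the gene of radixin, stood at 181 CPM in the wild-type and 156 CPM in the knockout library, a relative log2 ratio of 0.08. Ezr (chromosome 17, 7005440 to 7050611), the gene of ezrin, was low in both, at 9.81 and 13.1 CPM (0.72, 0.54 to 0.89, but 0.46 after thinning, under the 1.5-fold rule). Of 13 measured ERM proteins and partners, 3 were higher, 2 lower and 8 within 1.5-fold (1 higher and 6 lower on the CPM scale). Slc9a3r1, a scaffold that binds ERM proteins, went from 43.0 to 85.3 CPM (1.28), while Stk10, a kinase of ERM proteins, went from 91.8 to 46.4 CPM (−0.69, but −0.37 with the mixed cluster 8 counted in and −0.03 over all kept cells) and Nf2, the gene of the related protein merlin, from 25.3 to 14.1 CPM (−0.55, within the rule). The list median was −0.28, at percentile 1.28 of random lists. The list holds Msn itself, and without Msn the median of the 12 others was −0.17, at percentile 6.65. Among random lists also matched on gene span, a matching chosen after the data had been seen, the percentiles were 17.6 with Msn and 47.9 without it.

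Genes of the actin cytoskeleton did not leave the range of random lists in knockout microglia-like cells, although some members were higher. Of 25 genes of the actin cytoskeleton and motility, 9 were higher, none lower and 16 within 1.5-fold, but on the CPM scale 3 were higher and 5 lower. Tmsb10, a thymosin that binds actin monomers, went from 99.0 to 210 CPM (1.38), Actg1, gamma-actin, from 852 to 1644 CPM (1.24), and Vim, vimentin, from 5.42 to 11.96 CPM (1.44). Wipf1, a partner of the actin regulator WASP, went from 99.9 to 56.4 CPM (−0.53). The list median of 0.46 lay at percentile 92.9. Vimentin and Tmsb10 are abundant in monocytes, and the summed monocyte markers in microglia-like cells were 15.9 CPM in the wild-type and 27.9 CPM in the knockout library, 0.134% and 0.366% of their level in monocyte-like cells. Markers of other cells differed more between the libraries, with NK cell markers at 0.632 and 11.7 CPM, choroid plexus and ependymal markers at 1.60 and 13.4 CPM and erythroid markers at 83.5 and 438 CPM.

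Microglial identity genes were largely retained in the knockout library. The 12 microglia markers summed to 28977 CPM (wild-type) and 29263 CPM (knockout), although these genes also served to name the cells. Of 16 homeostatic genes, 3 were higher, 2 lower and 11 within 1.5-fold (CPM scale: 1 higher, 3 lower), with a median of 0.23 at percentile 16.1. Sall1, a transcription factor of microglial identity, went from 323 to 156 CPM (−0.76), and the purinergic receptor gene P2ry13 from 536 to 274 CPM (−0.67), while Cst3, cystatin C, went from 39531 to 65582 CPM (1.02). Disease-associated genes did not shift as a group: of 14 measured, 4 were higher, 1 lower and 9 within (CPM scale: 0 higher, 2 lower), with a median of 0.26 at percentile 56.7. Trem2, a lipid-sensing receptor, stood at 1912 and 2588 CPM (0.73), and Csf1, a microglial growth factor, at 83.6 and 42.3 CPM (−0.69). Lpl (−0.42) and Clec7a (−0.19) lay within 1.5-fold.

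Complement, phagocytosis, lysosomal and lipid genes each had members that differed, but none of their list medians left the range of random lists. Of 8 complement genes, 4 were higher and 4 within (CPM scale: 1 higher, 1 lower), among them the initiator chains C1qa (8195 to 11927 CPM, 0.84), C1qb (0.88) and C1qc (0.93), with a median of 0.32 (percentile 50.2). Of 19 phagocytosis genes, 5 were higher, 2 lower and 12 within (CPM scale: 0 higher, 5 lower), with a median of 0.12 (percentile 16.5). The 2 lower were Itgav, an integrin chain (137 to 68.7 CPM, −0.70), and Dock2, a Rac activator (215 to 110 CPM, −0.67), while Mertk, a receptor for apoptotic cells, went from 671 to 395 CPM (−0.47). Of 25 lysosomal genes, 3 were higher and 22 within (CPM scale: 0 higher, 0 lower), with Ctsf at 0.77, Npc2 at 0.63, Tpp1 at −0.19 and Lamp2 at −0.06, and a median of 0.22 (percentile 20.2). Of 15 cholesterol and lipid genes, 3 were higher, 1 lower and 11 within (CPM scale: 0 higher, 6 lower), with a median of −0.18 (percentile 7.34). The 1 lower gene was Abca1, a cholesterol exporter, at 336 and 160 CPM (−0.78), while Npc1 lay at −0.45 and Lrp1 at −0.40. Of 14 neuron-microglia signalling genes, 2 were higher, 1 lower and 11 within (CPM scale: 0 higher, 3 lower), with a median of −0.07 (percentile 3.99). The 1 lower gene was Tgfbr2, a receptor for TGF-beta, at 326 and 162 CPM (−0.71), and the fractalkine receptor gene Cx3cr1 stood at 5357 and 3586 CPM (−0.28), Tgfbr1 at −0.30 and Adam17 at −0.52. The calls of P2ry13, Csf1, Itgav, Dock2 and Tgfbr2 were near the rule and lay under it, at −0.54, −0.55, −0.57, −0.53 and −0.58, relative to the median of all genes with 1 UMI in each library. Over all kept cells Trem2 (0.56) and Ctsf (0.57) lay under it, as did Npc2 (0.55) relative to genes at 30 CPM.

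Interferon-response genes were the list with the highest median in knockout microglia-like cells. Of 12 measured, 9 were higher and 3 within (CPM scale: 6 higher, 0 lower), with a median of 0.89 at percentile 100. Isg15, a ubiquitin-like modifier, went from 25.4 to 49.6 CPM (1.26), Irf7, a transcription factor of the response, from 9.08 to 17.4 CPM (1.23), and Ifi27l2a from 58.4 to 94.4 CPM (0.99). Monocyte RNA at the level of the monocyte markers would account for at most 59.8% of the CPM difference of Ifitm3, 40.2% of that of Ifi27l2a, 28.9% of that of Irf7 and 3.51% of that of Isg15. No such limit was computed for border-associated macrophage RNA, so a part from that class is not excluded. Markers of that class summed to 285 CPM in wild-type and 255 CPM in knockout microglia-like cells, 4.13% and 4.24% of their level in the class itself.

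Immediate early, heat shock and inflammatory genes went both ways, with more of the immediate early and heat shock genes higher than lower. Of 23 genes of the immediate early and dissociation response, which tissue digestion is known to induce, 12 were higher, 1 lower and 10 within (CPM scale: 8 higher, 2 lower), with a median of 0.67 at percentile 98.7. Dnajb1, a heat shock co-chaperone, went from 228 to 461 CPM (1.31), next to Hspa1a, Hspa1b and Klf2. Of the immediate early transcription factors, chosen as examples after their values were seen, Fos lay at 1.05 and Junb at 1.18, but Jun at 0.49, Fosb near 0 and Egr1 at −0.32, and Btg2 (−0.67) was the 1 lower gene. The list median lay at percentile 73.9 when random lists were also matched on gene span, a matching chosen after the data had been seen. Of 17 genes of inflammatory cytokines and NF-kB signalling, 5 were higher, 1 lower and 11 within (CPM scale: 2 higher, 3 lower; median 0.23, percentile 57.8). Nfkbia, the inhibitor of NF-kB, went from 1214 to 1898 CPM (0.94) and the chemokine gene Ccl7 from 9.56 to 15.1 CPM (0.95), while Nfkbiz went from 463 to 244 CPM (−0.63, but −0.48 over all kept cells) and Tnfaip3 from 312 to 180.0 CPM (−0.50). Of 12 antigen presentation genes, 6 were higher and 6 within (CPM scale: 1 higher, 0 lower), with Psmb8, an immunoproteasome subunit, at 179 and 271 CPM (0.89), the invariant chain gene Cd74 at 80.3 and 115 CPM (0.82), Cd80 at −0.29 and Cd86 at −0.14. Their median was 0.53 (percentile 97.2). Of 5 measured proliferation genes, 1 was higher, Stmn1 (12.1 to 22.0 CPM, 1.16), and 4 were within, among them Pcna (−0.21), Tyms (0.56) and Hmgb2 (0.25), with a median of 0.25 (percentile 78.7).

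**Figure D4:**
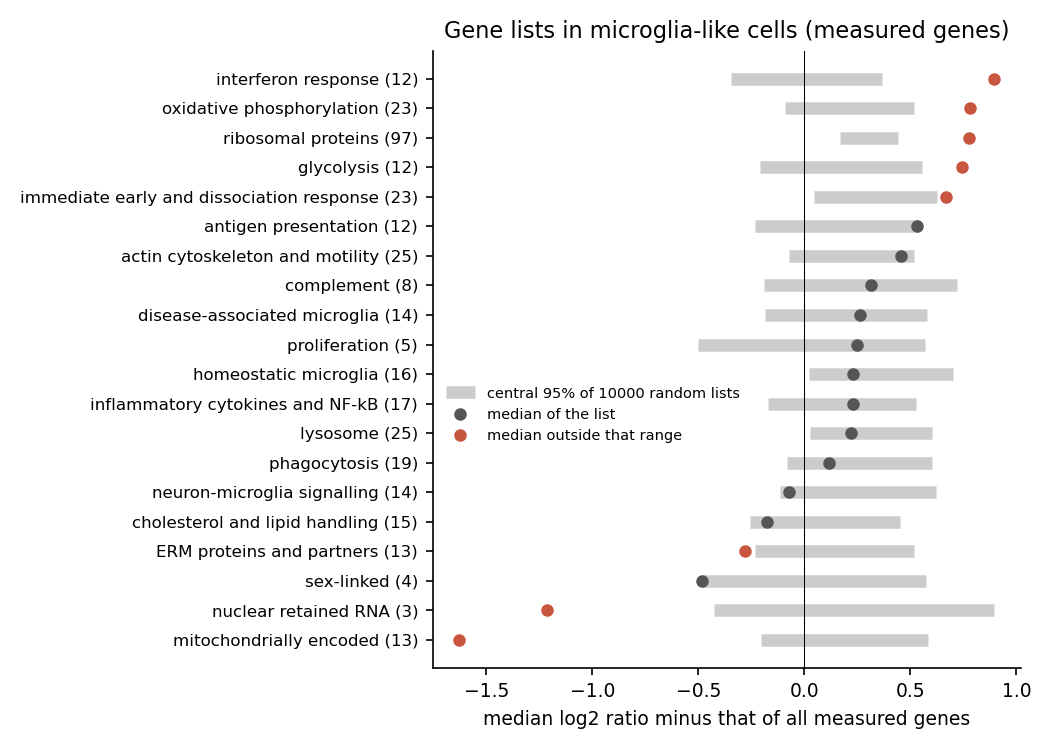
Median log2 ratio of each of 20 gene lists in microglia-like cells minus that of all measured genes, with the number of measured genes in brackets and grey bars for the central 95% of 10000 random lists matched on expression. Red points lie outside that range: 5 lists lie above it, led by interferon response at 0.89, and 3 below it, lowest for mitochondrially encoded genes at −1.63.

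Genes of energy metabolism and translation encoded in the nucleus were higher, and mitochondrially encoded RNA lower, in knockout microglia-like cells. Of 23 nuclear-encoded oxidative phosphorylation genes, 22 were higher and 1 within (CPM scale: 8 higher, 0 lower; median 0.78, percentile 100), with the complex III subunit Uqcrc1 at 63.5 and 123 CPM (1.25), Ndufa3 of complex I at 84.3 and 148 CPM (1.11), Uqcrq at 1.08 and Cox8a at 0.98. Of 12 glycolysis genes, 9 were higher and 3 within (CPM scale: 3 higher, 0 lower; median 0.74, percentile 99.9), with Gapdh at 428 and 873 CPM (1.32), Eno1 at 0.99, Ldha at 0.96 and Pgam1 at 0.78. Of 97 measured genes with ribosomal protein symbols, which include pseudogenes and S6 kinases, 64 were higher, 3 lower and 30 within (CPM scale: 38 higher, 6 lower; median 0.78, percentile 100). Of the 85 that code for protein and are not S6 kinases, a choice made after the data had been seen, 61 were higher, 1 lower and 23 within (median 0.80, percentile 100), with Rps26 at 281 and 579 CPM (1.34) and Rpl36 at 348 and 712 CPM (1.33). The pseudogenes Rps3a3 and Rps10-ps2, whose reads could be shared with their parent genes, lay at 1.46 and 3.00. All 13 mitochondrially encoded genes had a ratio below the median, 12 of them by the rule (median −1.63, percentile 0), with the small ribosomal RNA mt-Rnr1 at 1276 and 216 CPM (−2.27), mt-Atp6 at −2.52, mt-Nd6 at −2.33 and mt-Atp8 at −2.31. Of 3 nuclear retained RNAs, Neat1, the scaffold of paraspeckles, went from 399 to 132 CPM (−1.30) and Kcnq1ot1 from 209 to 73.7 CPM (−1.21), while Malat1 lay at 0.17 (median −1.21, percentile 0.02). Of 4 sex-linked genes, all Y-linked, Kdm5d (19.95 to 8.17 CPM, −0.99) and Uty (29.0 to 14.02 CPM, −0.75, but −0.53 after thinning) were lower, while Eif2s3y (−0.21) and Ddx3y (0.07) were within (median −0.48, percentile 2.57), and Xist and Tsix lay under 10 CPM in both libraries.

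Genes of short genomic span had higher ratios than genes of long span. Over 5 equal bins of 8683 measured genes with median spans of 4.58, 13.2, 25.3, 46.3 and 109.6 kb, median relative log2 ratios were 0.39, 0.25, 0.06, −0.15 and −0.35. With random lists matched on span as well as expression, a choice made after the data had been seen, 4 lists lay above and 2 below the central range, in place of 5 and 3.

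**Figure D5:**
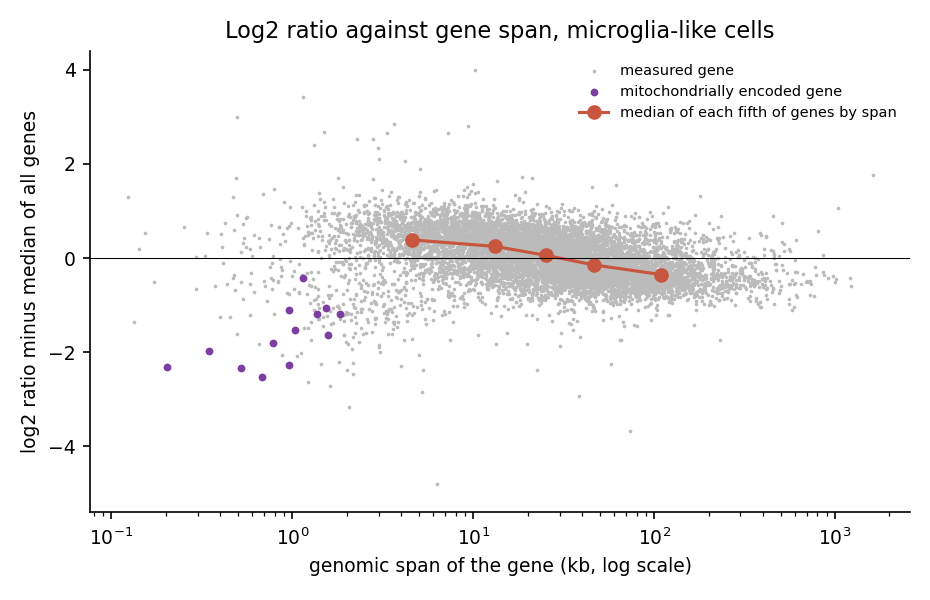
Relative log2 ratio against genomic span in kb on a log axis for measured genes in microglia-like cells (grey), with mitochondrially encoded genes in purple and the median of each of 5 span bins in red. The medians go from 0.39 at 4.58 kb to −0.35 at 109.6 kb, and the mitochondrially encoded genes, although short, lie below 0.

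State genes of microglia were found in shares of microglia-like cells that mostly differed by less than 1.5-fold between the libraries. After thinning, 1 of 20 state genes was found in a share of cells at least 1.5-fold higher in the knockout library, Isg15 at 4.62% (4.06 to 5.25) and 7.98% (7.19 to 8.84), against 18.6% and 23.4% without thinning. In 87 knockout NK cell-like cells, of which 84 were thinned and 3 left out (median 4001 UMIs), 5.95% (1.96 to 13.3) had an Isg15 UMI. That share was above the wild-type microglial share, with an interval that held the knockout share. These cells came from the knockout library and were not shown to lack Isg15, so they set no background. Whether the Isg15 shares stand above a background stayed open. The 4 genes with lower shares were rare: the cytokine gene Il1b at 1.09% (0.820 to 1.42) and 0.685% (0.459 to 0.982) (4.33% and 2.87% unthinned), the integrin gene Itgax at 0.949% (0.698 to 1.26) and 0.614% (0.402 to 0.899) (5.53% and 2.30%), the matrix protein gene Spp1 at 0.525% (0.343 to 0.768) and 0.307% (0.164 to 0.525) (2.42% and 0.941%) and the cycle gene Mki67 at 0.283% (0.155 to 0.474) and 0.0709% (0.0146 to 0.207) (1.45% and 0.175%). The intervals of Il1b, Itgax, Spp1 and Mki67 overlap between the libraries. In the thinned knockout NK cell-like cells Itgax was found in 14.3% (7.61 to 23.6), above both microglia-like shares, so these cells set no background for Itgax. Spp1 was found in 2.38% (0.290 to 8.34) of them, Mki67 in 1.19% (0.0301 to 6.46) and Il1b in none of 84. Those were too few cells to set a background for Spp1, Mki67 and Il1b. Apoe was found in 37.1% of wild-type and 45.5% of knockout cells (68.4% and 68.0% unthinned), with 21.4% in NK cell-like cells. Cd74 was found in 11.3% and 15.6% (37.8% and 39.1% unthinned), against 10.7% in NK cell-like cells. Ccl3 and Ccl4, chemokine genes that NK cells also express, were found in 56.9% and 50.5% and in 62.3% and 60.5% of thinned cells (77.9% and 68.5%, and 80.1% and 74.3%, unthinned). C1qa and Fos were found in over 99% of cells in both libraries, shares too near their limit to differ, although Fos stood at 7460 and 12591 CPM. The shares of Cst7, Lpl, Clec7a, Tnf, Ifit3, H2-Ab1, Cd68, C3 and Top2a differed by less than 1.5-fold.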

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

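The tests on blood carryover, on a lower microglial share alone, on free RNA and on the mitochondrially encoded part of the RNA pattern were chosen after the result was seen, and the others were written before their own value was computed but after the expression ratios had been looked at.

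Barcodes under 500 genes, which no comparison used, held hemoglobin RNA in the knockout library. Hemoglobin genes made up 9.97% (9.91 to 10.0) of the UMIs of the 1463 such knockout barcodes and 0.839% of those of the 207 wild-type barcodes, at a median of 628 UMIs in both. Malat1 made up 5.95% against 5.52% of these UMIs, and mitochondrially encoded genes 2.30% against 9.48%.

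Blood and border classes together had higher shares in the knockout library. A lower share of microglia alone would give every other class the same fold, but the counting interval of the monocyte-like fold began at 7.11 and that of the border-associated macrophage-like fold ended at 4.48. Cell filters did not account for it either, since the lowest monocyte-like fold under them was 9.05. The fold was 9.32 with called doublets kept and 9.01 without the highest 6% of doublet scores. The doublet caller had not worked, so these settings could not decide whether doublets played a part. Blood carried over with the tissue may account for the blood classes: the monocyte-like fold was 2.82 times that of border-associated macrophages, which are not blood cells, and hemoglobin RNA was higher in the same library. It would not give a higher share of border-associated macrophages themselves, and the fold of that class had a lower bound of 2.46. Yet the class also holds cluster 10, with Ccr2, a monocyte marker, and Cd209a, a dendritic cell marker, among its leading genes. Blood carryover is therefore not excluded for cluster 10, but that cluster alone does not give the higher share of the class. With cells holding microglial RNA counted in, cluster 10 held 0.917% of wild-type and 1.95% of knockout cells. Cluster 6, led by Pf4 and Mrc1, held 1.78% (1.45 to 2.16) and 5.98% (5.46 to 6.54), and cluster 9 held 0.701% and 3.66%. A change in border-associated macrophages or in dissection of the meninges, or an effect of genotype on leukocyte entry, was not tested.

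The mix of RNA differed in one pattern over genes: nuclear-encoded oxidative phosphorylation, glycolysis and ribosomal protein genes higher, long genes, Neat1, Kcnq1ot1 and mitochondrially encoded RNA lower in the knockout library, while Malat1, the most abundant nuclear retained RNA, lay at 0.17. The long genes follow a gradient over gene span, with a Spearman correlation of −0.40 across genes, which are not independent replicates. Yet among random lists matched on expression and span, oxidative phosphorylation lay at percentile 99.92, glycolysis at 99.91 and ribosomal proteins at 100. The nuclear retained list, with Malat1 in it, lay at percentile 0.005. That matching was chosen after the data had been seen. These values argue against gene span as the whole cause for these lists. The mitochondrially encoded genes are short and had a median CPM log2 ratio of −1.92 (−1.63 relative to all genes), against the span gradient. Whether the ribosomal part was a change of microglia alone stayed open: these genes lay 0.53 above the median of all genes in border-associated macrophage-like cells, a class redefined after its levels had been seen, and past the bound set beforehand, but that bound ignored that random lists of like expression there reached 0.54. For the mitochondrially encoded part, the list lay at −1.46 in monocyte-like and −1.53 in border-associated macrophage-like cells, at percentile 0 in both. These values argue against a change of microglia alone but do not exclude it, since free microglial RNA was not accounted for. Wild-type cells of these classes held microglia markers at medians of 1699 and 3550 CPM. In barcodes under 500 genes, mitochondrially encoded genes made up 9.48% of wild-type and 2.30% of knockout UMIs. After thinning, the ribosomal list still lay 0.68 above the median, beyond the 0.41 of random lists, so it did not rest on the greater weight of deep cells. Thinning keeps each cell's expected mix of RNA, however. It could therefore not decide whether the pattern goes with depth per cell, which stays open. Also open is a difference in lysis, in loss of mitochondrial RNA or in library preparation between the 2 libraries, which the design confounds with genotype. An effect of genotype on all myeloid cells is open too.

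Msn RNA did not vanish from the knockout library. Wild-type cells mixed into it would leave cells with many Msn UMIs, but 0 of 4233 thinned knockout cells had 3 or more where 7.78 were expected, a ratio of 0 with an upper bound of 0.474. That bound replaced the plain ratio after the count of 0 had been seen. It lies under the 0.5 set beforehand for wild-type cells as the cause but not under the 0.2 set for ruling them out, so such cells are excluded as the whole source and not as a part. Free RNA would give a similar number of UMIs per cell in every class, so its CPM would be higher in shallower cells. Knockout monocyte-like and microglia-like cells had medians of 5237 and 5658 UMIs, yet monocyte-like cells held 2.75 times the Msn level of microglia-like cells (2.37 to 3.18). Free RNA as a part is not excluded: Msn stood at 32.0 CPM (20.7 to 47.2) in the shallow knockout cells of microglia-like cluster 7 and at 19.5 CPM (17.2 to 21.9) in those of cluster 0, with overlapping intervals. Barcodes shared with the wild-type library numbered 5 of 4570, and the cells without them kept 99.97% of the Msn level. The ratio between classes in the knockout library follows that in the wild-type library, so the values suggest RNA transcribed from the altered locus at 5.62 to 6.64% of the wild-type level, or reads of similar genes assigned to Msn, hypotheses that were not tested.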

How the results depend on the processing

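The alternatives on the highest doublet scores, the mixed cluster, cells with microglial RNA, hemoglobin, list membership and gene span were chosen after seeing the data. The rule that names clusters was revised after large microglial clusters had stayed unnamed without the mitochondrial filter and with at least 1000 genes, so the small moves of shares under these settings are partly built in. Of 96 named genes, 73 passed the 1.5-fold rule relative to the median of all genes and 0 of these changed sign over up to 15 settings, but 12 lay under the rule in at least 1, among them Ezr (0.46 thinned), Uty (−0.53 thinned), Stk10 (−0.03 over all kept cells) and Trem2 (0.56 over all kept cells). On the CPM scale 75 passed and 0 changed sign, nor did the median of any of the 8 lists outside the random range over up to 17. The sign does not set a list's call, and some calls moved. Lists above the random range numbered 4 to 7 and lists below it 2 to 4 over the settings. Msn ranged from −3.98 to −3.54 on the log2 scale, with −3.78 over all kept cells and −3.54 with median-of-ratios scaling. The microglia-like share in the wild-type library was 94.1% with at most 5% mitochondrial UMIs and 93.9% with at least 1000 genes. In the knockout library it was 67.0% with at least 1000 genes, 62.9% without the highest 6% of doublet scores and 65.7% with the mixed cluster counted in. The monocyte-like fold was 12.6 at resolution 0.3, and the border-associated macrophage-like fold ranged from 2.68 to 3.80. The cause of these moves was not tested. Genes higher numbered 729 over all kept cells, 1907 with median-of-ratios scaling, 2063 with a floor of 1 UMI in each library and 54 at 2-fold. Genes lower numbered 599 with that scaling, 1417 at 30 CPM, 8745 with the floor of 1 UMI and 631 at 2-fold. A scaling factor shifts all ratios at once, and the floor and the fold set how many genes can be counted, whereas the cause of the count over all kept cells was not tested. The median log2 ratio of all genes ranged from −0.43 to 0.14. State genes with a higher share numbered 3 without the mitochondrial filter, 4 when thinned to 1000 UMIs and 0 without thinning, and those with a lower share 7 without thinning. Unthinned shares also depend on depth, which was greater in wild-type cells, but depth is not the whole account of the 7. Four-way CPM values were lower too, at 26.9 and 16.4 for Lpl, 8.18 and 3.26 for Spp1, 6.10 and 3.16 for Itgax and 1.37 and 0.209 for Mki67. Clec7a, Il1b and C3 lay within 1.5-fold in CPM. The cause of the count without the mitochondrial filter was not tested. The number of cells limits the classes with 1 to 3 wild-type cells, whose folds have wide counting intervals.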

Other observations

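The test on glucocorticoid targets was written before its value was computed but after Tsc22d3 and Ddit4 had been seen, while the basophil genes and the splits by cluster were chosen after the data had been seen.

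Several stress genes that were higher in knockout microglia-like cells were also higher in monocyte-like and border-associated macrophage-like cells. Relative to the median of all genes in each class (−0.24 over 7650 genes in monocyte-like and −0.25 over 8995 genes in border-associated macrophage-like cells), Klf2 had log2 ratios of 1.94 and 1.62, Hspa1a of 1.53 and 2.10, and Tsc22d3 of 1.36 and 1.80. Ddit4 did not follow in monocyte-like cells, where it lay at 0.52, within the rule, with a CPM interval that included no difference (−0.11 to 0.69). In border-associated macrophage-like cells Ddit4 was higher, at 6.51 and 126 CPM (4.53), with a wide CPM interval (2.40 to 7.34). Nfkbia stood at 840 and 1929 CPM in monocyte-like cells (1.44) and at 813 and 1930 CPM in border-associated macrophage-like cells. Of 23 immediate early and dissociation genes, 15 were higher and 1 lower in monocyte-like cells (median 0.75, percentile 99.98 of random lists). In border-associated macrophage-like cells 13 were higher and none lower, but the median of 0.64 lay at percentile 88.6, inside the range of random lists. Glycolysis genes were higher too, with list medians of 0.62 and 0.86, and mitochondrially encoded genes were lower, with medians of −1.46 and −1.53. In monocyte-like cells the oxidative phosphorylation and ribosomal protein lists stayed inside the random range (percentiles 90.4 and 94.5). In border-associated macrophage-like cells the oxidative phosphorylation list lay above it (median 0.79, percentile 99.7), with 17 of 23 genes higher and 0 lower. The ribosomal protein list there stayed inside it (percentile 95.4). Neat1 lay at −1.54 and −1.29, and Cwc22 at −1.05 and −1.94. These values rest on 58 and 56 wild-type cells.

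Ezr was higher in knockout monocyte-like cells, whereas interferon genes depended on the cluster. Over all monocyte-like cells the interferon-response list lay low (median −0.16, percentile 0.93 of random lists), but cluster 5 held 60.3% of the wild-type and 82.0% of the knockout cells. Within cluster 5 its median was 0.48 (percentile 96.9), with 7 of 20 genes higher and 0 lower. Within cluster 11 its median was 0.10 (percentile 19.9), with 0 of 20 genes higher and 6 lower. Both medians lay inside the central range, but how much of the low value came from the different mix of clusters was not computed. In border-associated macrophage-like cells 9 of 20 interferon-response genes were higher and 2 lower (median 0.50, percentile 97.3, inside the central range). The immediate early and dissociation list of monocyte-like cells stayed above random lists within cluster 5 (0.91) and within cluster 11 (0.80). Ezr, the gene of the ERM protein ezrin, stood at 117 CPM (87.0 to 155) in wild-type and 291 CPM (275 to 307) in knockout monocyte-like cells, a CPM log2 ratio of 1.31 (0.90 to 1.75). It was 1.13 (0.60 to 1.71) within cluster 5 and 1.33 (0.69 to 2.04) within cluster 11, so that a different mix of clusters does not give it. In border-associated macrophage-like cells Ezr stood at 114 and 144 CPM, with an interval that included no difference (−0.19 to 0.91) and overlapped that of monocyte-like cells. Rdx stood at 82.1 and 67.2 CPM in monocyte-like cells, also with an interval that included no difference (−0.80 to 0.26), and at 74.8 and 125 CPM in border-associated macrophage-like cells, with a CPM log2 ratio of 0.74 (0.10 to 1.44). Of 5 basophil genes, at least 3 were found in 16 of 7571 knockout cells (0.211%, 0.121 to 0.343) and in 2 of 5562 wild-type cells (0.0360%).

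Tsc22d3 and Ddit4, both induced by glucocorticoids, were among the highest genes in knockout microglia-like cells, which raised the hypothesis of a stress hormone response in the mice of that library. Of 12 other glucocorticoid targets, 7 were measured, 4 of them higher and 3 within 1.5-fold relative to the median, with Fkbp5 at 1.08, Cdkn1a at 0.90, Mt1 at 0.86 and Per1 at 0.64. Cited2 (0.11), Errfi1 (0.03) and Sesn1 (−0.19) did not follow. Their median lay at percentile 93.7 of lists matched on expression and span, between the bounds set beforehand, so such a response cannot be told apart from the wider shift of RNA with 7 genes and 1 library per genotype.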
